A study of Drosophila melanogaster with 36 samples.

How the data were processed

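Whole adult flies of the strains OregonR, Antp73b and ap56f came from a commercial supplier, per the labels. Total RNA was extracted, and 200 ng of poly(A)-selected mRNA was made into Cy3-labelled cDNA (probe 1) or Cy5-labelled cDNA (probe 2) with random primers and a custom kit, per the labels' protocols. Arrays were scanned on a GenePix 4000A scanner, per the labels' protocols, and the later signal processing is not given in the sources used here. The deposited table holds 1 signed fold ratio between the channels of an array per spot. This unit was read from the deposited values themselves: of 1059750 values 0 lay between -1 and 1, all had 1 decimal, and they ran from -11.2 to 9.9. A fold of 1 or -1 made up 19.1% of the values, and the smallest step next to it was 0.14 on the log2 scale. The labels do not say which channel a positive fold favours. Log2 ratios were computed as the sign of the value times the log2 of its size, coded as channel 1 over channel 2, and each array was centred on its median.

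Spots were joined into elements by the probe table, which lists every element at a pair of positions 468 to 676 places apart within 24 blocks. All 12660 elements listed with a gene or accession had the same gene and accession at both spots. Elements without a listed gene were paired by the same layout, and the values of both spots were averaged. Gene symbols came from the platform's probe table and were updated for 12107 elements through a RefSeq gene table of Drosophila assembly Release 6, which was also used for chromosome arms and for which genes lie beside each other. An element was tested if at least 2 of the 4 arrays of each of the 9 groups had a value, which left out 866 elements and kept 14866, of which 12795 had a value on all 36 arrays. Duplicate spots correlated across elements with r between 0.1898 and 0.8335 per array (median 0.579), and arrays of a group correlated with r between 0.42 and 0.724.

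The model was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without trend or robust options, two-sided). It had a dye intercept and a term for each mutant strain, coded 1 for the strain in channel 1 and -1 for the strain in channel 2, over all 36 arrays. P-values were adjusted by the Benjamini-Hochberg method over the elements tested, with a threshold of 0.05, and an element past it is called. A strain stood apart on an element if it was called against both other strains on the same side. Direct and indirect differences were compared by a contrast around the triangle of strains. Named genes were chosen by a rule: in each comparison, the 10 genes with the largest difference on each side among called elements with 1 gene and the same side on all direct arrays with a value (at least 6 of 8), the genes Antp and ap whatever their p, and in each gene list the 4 called members with the smallest p. Genes said to lead a list were therefore chosen by p and not by the size of the difference. For a gene with several elements, the 10 largest were ranked by its element with the largest difference. Means, SDs and sides of direct arrays were taken from turned ratios with the dye offset left in. Such an offset adds to 1 orientation and subtracts from the other, so it widens these SDs and can split the sides.

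Gene lists of 20 functions were tested with camera at an inter-gene correlation of 0.01 and with an estimated correlation, and with fry, using 1 element per gene with a value on all arrays. The p-values were adjusted over 60 tests of lists and comparisons. For each list the called members were counted over all elements and adjusted over the list alone. Counts cover all tested members, and the set tests could cover fewer, such as 12 of 13 immune effectors and 65 of 73 cytochrome P450 genes. Some lists were fixed at many more genes than were tested, such as 44 for immune effectors and 23 for 14 tested egg shell and yolk genes. Chromosome arms were compared with Fisher's exact test, adjusted over 18 tests. The spread of self-hybridised arrays was compared by a permutation test with 100000 resamples. Place in the group (the first 2 or last 2 arrays by array number) and parity of the array number were found in the data and treated as batches, by blocks, by fits within each batch and by interaction terms. Calls from 1 orientation were read in the other, a comparison added after the data were seen. The deposited table held 0 columns of other samples, and no array was left out.

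The steps were tested on simulated data with known answers, drawn for 14866 elements with the spread of the arrays. In Antp73b against OregonR, 60 of 67 elements changed by 0.3 on the log2 scale were called on the right side, as were 67 of 67 changed by 0.6 and 66 of 66 changed by 1, and 16 unchanged elements were called. For the simulated comparison of ap56f with OregonR, in which nothing changed, limma called 0 elements. The comparisons, the model, the lists, the naming rule and most alternatives were chosen before the data were examined. Those alternatives were other centring and scaling, other filters and thresholds, a minimum fold, limma's trend, robust and array weight options, subsets of arrays, no dye term and leaving out each array in turn.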

Results

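Transcript abundance was compared between 3 strains of adult Drosophila melanogaster on 36 arrays, each hybridised with RNA in 2 colours. OregonR is a wild-type strain. Antp73b carries an allele of Antennapedia (Antp), a homeotic gene whose expression in the head turns antennae into legs. The strain ap56f carries an allele of apterous (ap), a homeodomain gene needed for wing development. Every ordered pair of strains in channel 1 and channel 2 was hybridised on 4 arrays, which makes 9 groups. In 3 of these groups (12 arrays) a strain was hybridised against itself, and in the others (24 arrays) 2 strains were compared with the colours exchanged between groups. The sex of the flies and the number of RNA extractions are not given in the sources used here, so p-values measure only the spread between arrays, which may be technical.

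Each array held 31464 spots, which were 15732 elements spotted as pairs, and 26362 to 30716 spots per array had a value. The table listed 12587 elements with 1 gene, 73 with several and 3072 with none, and whether those with none are controls is not given in the sources used here. Of the 14866 elements tested, 11998 stood for 1 gene, and 10477 genes were tested in all. The number of arrays limits the precision: the median standard error (SE) of a strain difference was 0.058 on the log2 scale. Which channel a positive value favours is not given in the sources used here. Differences are therefore given by side: if the ratio is channel 1 over channel 2, the plus side means more transcript in the strain named first, and if it is the opposite ratio it means less. The scale of the values was plain from the numbers, and what centring was done before deposit is unknown: the median signed fold was 1 or -1 on 32 arrays and 1.1 on 4.

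Self-hybridised arrays give the background. The standard deviation (SD) of log2 ratios across elements averaged 0.261 ± 0.0353 (SD, n = 12) on these arrays and 0.328 ± 0.0537 (SD, n = 24) on arrays of 2 strains (two-sided permutation test, p = 0.00048). With the median absolute deviation in place of the SD the means were 0.225 and 0.28 (permutation p = 0.0217). Between 0.671% and 0.912% of elements lay beyond 2-fold on self-hybridised arrays, and 0.762% to 1.96% on arrays of 2 strains. Among elements listed with 1 gene these shares were 0% to 0.159% (0 to 18 elements) and 0.0966% to 1.08% (12 to 131), so most elements beyond 2-fold on self-hybridised arrays, 101 to 118 per array, were others. Arrays also differed by their place in the group. The SD averaged 0.265 on the first 2 arrays of a group by array number and 0.346 on the last 2 (n = 18 each), and it was higher in the last 2 in 9 of 9 groups (exact sign test, two-sided, p = 0.00391). In addition, 120 spots had no value on any odd-numbered array and a value on every even-numbered array, and 19 showed the reverse. Place and parity of the array number were therefore treated as batches, and both fell evenly across the groups. The arrays of each group carried consecutive array numbers. An effect shared by such a run of arrays cannot be told apart from that of its strain pair and orientation. Blocks by place or parity do not remove it.

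**Figure D1:**
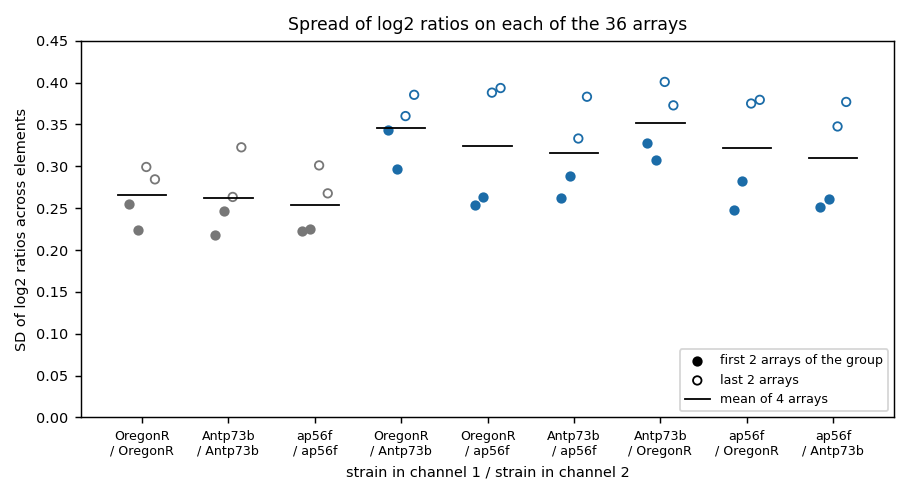
SD of log2 ratios across elements (vertical axis, log2 units) on each of 36 arrays, by the strains in channel 1 and channel 2; filled points are the first 2 arrays of a group, open points the last 2, bars the mean of 4 arrays. Self-hybridised arrays averaged 0.261 and arrays of 2 strains 0.328.

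Across the comparison of Antp73b with OregonR, the named genes included those of digestive enzymes, lysozymes, lectins, antimicrobial peptides and egg shell proteins. On the plus side stood tobi, an alpha-glucosidase regulated by dietary sugar and protein, the C-type lectin lectin-37Da, and Mtk and DptB, which encode antimicrobial peptides made in the fat body. On the minus side stood the gut lysozymes LysE, LysS and LysX, the C-type lectin lectin-28C, the cytochrome P450 Cyp6w1, the juvenile hormone binding protein Jhbp2 and the egg shell genes Cp38, Vm32E and yellow-g2. The gene Antp itself did not pass the threshold.

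tobi differed 6.71-fold (log2 2.75, SE 0.065, limma adjusted p = 1.8e-36), and its ratio on the 8 arrays that hybridised these strains directly averaged 2.78 ± 0.16 (SD, n = 8). LysE differed 6.8-fold on the other side (log2 -2.77, SE 0.061, limma adjusted p = 7e-38), with a direct mean of -2.74 ± 0.38 (SD, n = 8). The other genes named on the plus side were lectin-37Da (2.53), Mtk (2.41), CG4363 (2.26), CR14499 (1.98), DptB (1.65), CG16898 (1.56), CG11912 (1.55), the cytochrome P450 Cyp6a20 (1.51) and fit (1.45), a fat body peptide gene tied to feeding in females. On the minus side they were LysS (-2.39), Cyp6w1 (-1.87), lectin-28C (-1.49), Cp38 (-1.16), Vm32E (-1.11), Jhbp2 (-1.1), LysX (-1.07), yellow-g2 (-0.99) and CG4734 (-0.96). The rule by which these 20 genes were named requires the same side on the direct arrays; their limma adjusted p ran from 7e-38 to 1.4e-20. The difference of Antp was 0.14 (SE 0.06, limma adjusted p = 0.099), on the same side in 4 of 8 direct arrays, and that of ap was 0.07 (SE 0.067, limma adjusted p = 0.53). The count of 4 of 8 was made with the dye offset left in, so it may reflect the 2 orientations. The probe sequences are not given in the sources used here, so near-identical genes such as the lysozymes and the glutathione S-transferases of the GstD cluster may share signal.

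In all, 3277 of 14866 elements (22%) passed an adjusted p of 0.05 in limma, 1771 on the plus side and 1506 on the minus side, and they stood for 2618 genes. A gene was counted if any of its elements was called. Of 145 genes with more than 1 called element, 9 had called elements on opposite sides. In ap56f against OregonR this held for 6 of 81 and in Antp73b against ap56f for 5 of 98. Most differences were small: the median fold of the called elements was 1.17, with 201 at 1.5-fold or more, 47 at 2-fold or more (37 plus, 10 minus) and 7 at 4-fold or more. No gene was listed for 469 of the called elements, 16 of them at 2-fold or more. Within the batches 2664 elements passed in the first 2 arrays of each group, 1597 in the last 2, 1790 in even-numbered and 1732 in odd-numbered arrays. With place, parity or both as blocks the counts were 3578, 3342 and 3679.

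Gene lists fixed beforehand showed which functions were involved. The 14 egg shell and yolk genes included 12 called on the minus side and 0 on the plus side, led by Cp38, Femcoat (-0.85), Vm32E and dec (-0.93). The count adjusted over the list alone was also 12, the list median was -0.67, and within the 4 batches it ran from -0.74 to -0.59 (camera adjusted p = 2.1e-20). Ovary germline genes, which build and pattern the oocyte, had 14 of 22 on the minus side (16 on the minus side and 1 on the plus side adjusted over the list alone; median -0.20, camera adjusted p = 4.5e-09), among them gnu (-0.69), CycB (-0.61) and vas (-0.55). Genes of the male accessory gland and ejaculatory duct, whose products enter the seminal fluid, also lay on the minus side, with 7 of 20 called (8 adjusted over the list alone; median -0.09, camera adjusted p = 0.00038), including Acp53C14a (-0.62) and Acp62F (-0.54).

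Immune effectors lay on the plus side in the same comparison, with 9 of 13 called plus and 1 minus (9 and 1 adjusted over the list alone; median 0.25, camera adjusted p = 7.4e-06); beside Mtk and DptB they included the peptidoglycan recognition protein PGRP-SB1 (1.09). Cytochrome P450 genes, many of which break down foreign compounds, had 31 plus and 7 minus calls among 73 (33 and 10 adjusted over the list alone; median 0.08, camera adjusted p = 9.4e-06). Cyp28d1 (1.43) and Cyp6a2 (1.25) were among them. Glutathione S-transferases and UDP-glycosyltransferases, which conjugate such compounds, had 23 plus and 5 minus of 60 (26 and 5 adjusted over the list alone; median 0.12, camera adjusted p = 0.00041, and 0.11 with an estimated correlation), led by Ugt35A1 (0.86) and Ugt35C1 (0.75). Larval serum and fat body genes had 6 plus and 0 minus of 10 (6 adjusted over the list alone; median 0.20, camera adjusted p = 7.7e-05), including the alcohol dehydrogenase Adh (0.80) and the lipoprotein apolpp (0.48).

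Gut digestion genes went both ways, with 10 plus and 14 minus of 32 (the same adjusted over the list alone; median -0.08, camera adjusted p = 0.022, and 0.14 with an estimated correlation): the maltase Mal-A1 stood at 1.33 and the lysozymes on the minus side. Phototransduction genes had 5 plus and 1 minus of 17 (5 and 1 adjusted over the list alone; median 0.08, camera adjusted p = 0.043, and 0.13 with an estimated correlation), with the arrestins Arr1 (0.35) and Arr2 (0.34) plus and the channel trpl (-0.40) minus. Leaving out array 50, 63, 68, 71 or 72 took this list past 0.05, to between 0.054 and 0.065. Within the 4 batches the medians kept their side: -0.22 to -0.18 for ovary, -0.11 to -0.09 for accessory gland, 0.20 to 0.26 for immune, 0.09 to 0.13 for P450, 0.09 to 0.12 for conjugating enzymes, 0.18 to 0.21 for fat body, -0.10 to -0.07 for gut and 0.09 to 0.13 for phototransduction genes.

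The comparison of ap56f with OregonR involved several of the same functions. The mutated gene ap stood on the plus side. tobi, Mtk and DptB lay again on the plus side, joined by Cyp4e3, a cytochrome P450, Lectin-galC1, a galactose-binding lectin, and Ugt35C1, a UDP-glycosyltransferase. Cyp6w1, Jhbp2 and the egg shell gene Cp38 lay again on the minus side, with Cubn2, a cubilin-like receptor of protein uptake.

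The difference of ap was 0.27 (SE 0.067, limma adjusted p = 0.0029), with a direct mean of 0.29 ± 0.14 (SD, n = 8) and the same side on 8 of 8 direct arrays; within the last 2 arrays of each group and within even-numbered arrays its limma adjusted p was 0.065 and 0.2, with differences of 0.31 and 0.23. The labels do not say which part of ap the element covers, so it does not test the strain's label. Antp differed by 0.03 (SE 0.06, limma adjusted p = 0.79). Among the named genes, which leave out larger values of elements with no gene listed, the largest plus value belonged to tobi, 2.93-fold (log2 1.55, SE 0.065, limma adjusted p = 6.4e-25), with a direct mean of 1.52 ± 0.28 (SD, n = 8). The largest minus value belonged to Cyp6w1, 3.46-fold (log2 -1.79, SE 0.084, limma adjusted p = 3.5e-23), with a direct mean of -1.62 ± 0.41 (SD, n = 8). The other genes named on the plus side were Mtk (1.36), CG4757 (1.32), DptB (1.17), Sclp (1.16), Cyp4e3 (1.12), CG3699 (1.1), CG9360 (1.06), Lectin-galC1 (1.03) and Ugt35C1 (1.02). On the minus side they were CG13083 (-1.21), CG7953 (-1.14), CG17472 (-0.91), Jhbp2 (-0.87), CG4734 (-0.86), CG10680 (-0.82), Cubn2 (-0.81), Cp38 (-0.81) and CG7381 (-0.76). Their limma adjusted p ran from 6.4e-25 to 4e-14. The array values of Sclp, Ugt35C1, CG17472 and CG4734 each included an outlying array. Ugt35C1 is measured by more than 1 element: the element named for its gene list gave 0.73.

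limma called 2335 elements (15.7%), 1032 on the plus side and 1303 on the minus side, which stood for 1796 genes. The plus side held 44.2% of these calls, but 53.5% after quantile normalization and 53.6% after centring on a trimmed mean. The median fold of the called elements was 1.16, with 116 at 1.5-fold or more, 19 at 2-fold or more (16 plus, 3 minus) and 0 at 4-fold or more, while 4227 elements had an unadjusted p under 0.05 in limma. No gene was listed for 428 of the called elements, 6 of them at 2-fold or more. Within the batches 1460 elements passed in the first 2 arrays of each group, 876 in the last 2, 834 in even-numbered and 1347 in odd-numbered arrays. With place, parity or both as blocks the counts were 2583, 2389 and 2673.

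All 14 egg shell and yolk genes were called on the minus side in ap56f against OregonR (14 adjusted over the list alone; median -0.46, camera adjusted p = 2.3e-21), among them the yolk receptor yl (-0.62), dec (-0.61) and Femcoat (-0.51). Ovary germline genes had 10 of 22 on the minus side (11 adjusted over the list alone; median -0.12, camera adjusted p = 7.4e-06), led by me31B (-0.49). Accessory gland genes had 12 of 20 on the minus side (13 adjusted over the list alone; median -0.30, camera adjusted p = 1.6e-10), among them Acp53C14b (-0.75), Acp53C14a (-0.69) and the ejaculatory bulb protein EbpII (-0.54). Phototransduction genes had 8 plus and 1 minus of 17 (10 and 1 adjusted over the list alone; median 0.16, camera adjusted p = 1e-06), led by Arr2 (0.84), Arr1 (0.51) and the retinol dehydrogenase Pdh (0.40). Immune effectors had 8 plus and 1 minus of 13 (8 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 2.5e-06), with PGRP-SB1 at 0.73 and the antifungal peptide Drs at 0.70. Cytochrome P450 genes had 18 plus and 5 minus of 73 (22 and 6 adjusted over the list alone; median 0.06, camera adjusted p = 7e-04, and 0.11 with an estimated correlation). Within the 4 batches the medians ran from -0.50 to -0.44 for egg shell, -0.16 to -0.10 for ovary, -0.32 to -0.26 for accessory gland, 0.15 to 0.19 for phototransduction, 0.14 to 0.21 for immune and 0.01 to 0.09 for P450 genes.

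Between the mutant strains, Antp73b against ap56f, the named genes included lysozymes, lectins and gut proteases. lectin-37Da, tobi and the cytochrome P450 Cyp28d1 stood on the plus side. LysE, LysS, lectin-28C, the Jonah gut proteases Jon99Ci and Jon25Bii, and dyw, a gene that affects daytime sleep, stood on the minus side. The gene ap lay on the minus side by a small margin.

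CG4363 had the largest plus value, 4.18-fold (log2 2.06, SE 0.063, limma adjusted p = 1.9e-31), with a direct mean of 2.05 ± 0.40 (SD, n = 8). LysE had the largest minus value, 4.52-fold (log2 -2.18, SE 0.061, limma adjusted p = 6.4e-33), with a direct mean of -2.20 ± 0.27 (SD, n = 8). The other genes named on the plus side were CR14499 (1.95), CG7953 (1.71), lectin-37Da (1.71), Srg2 (1.48), CG42807 (1.35), Cyp28d1 (1.22), CG11912 (1.22), CG16898 (1.2) and tobi (1.19). On the minus side they were LysS (-1.92), CG12374 (-1.36), lectin-28C (-1.34), dyw (-1.24), CG18179 (-1.17), CG12998 (-1.17), Sclp (-1.03), Jon99Ci (-1.0) and Jon25Bii (-0.98). For these 20 genes limma adjusted p ran from 1.5e-34 to 6.7e-21. The difference of ap was -0.20 (SE 0.067, limma adjusted p = 0.029), on the same side in 5 of 8 direct arrays; without array 60 or 61 the limma adjusted p was 0.092 and 0.13 (differences -0.17 and -0.15), with the 8 direct arrays alone 0.19 (-0.19) and without a dye term 0.055 (-0.20). Within the first 2, even-numbered and odd-numbered arrays it was 0.59, 0.4 and 0.087 (-0.06, -0.17 and -0.24). The count of 5 of 8 for ap was made with the dye offset left in. Antp differed by 0.11 (SE 0.06, limma adjusted p = 0.25). The array values of CG16898 included an outlying array.

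limma called 2288 elements (15.4%), 1516 on the plus side and 772 on the minus side, which stood for 1833 genes. The plus side held 66.3% of these calls, but 50.6% after quantile normalization and 50.5% after centring on a trimmed mean, so the side on which most calls fell rests on the centring. The median fold of the called elements was 1.17, with 129 at 1.5-fold or more, 41 at 2-fold or more (29 plus, 12 minus) and 2 at 4-fold or more, CG4363 and LysE. Called elements with no gene listed numbered 327, of which 13 were at 2-fold or more. Within the batches 1732 elements passed in the first 2 arrays of each group, 935 in the last 2, 1051 in even-numbered and 1213 in odd-numbered arrays. With place, parity or both as blocks the counts were 2546, 2332 and 2598.

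Gut digestion genes split between the mutant strains, with 12 plus and 17 minus of 32 (13 and 19 adjusted over the list alone; median -0.21, camera adjusted p = 7.4e-06). Egg shell and yolk genes had 2 plus and 7 minus of 14 (2 and 8 adjusted over the list alone; median -0.19, camera adjusted p = 2.4e-05), with Vm32E at -0.46 and Cp38 at -0.35. Ovary germline genes had 1 plus and 5 minus of 22 (2 and 6 adjusted over the list alone; median -0.07, camera adjusted p = 0.0016), led by gnu (-0.35) and vas (-0.34). Glutathione S-transferases and UDP-glycosyltransferases had 22 plus and 4 minus of 60 (23 and 4 adjusted over the list alone; median 0.06, camera adjusted p = 4.5e-05, and 0.06 with an estimated correlation), among them GstD5 (0.57), Ugt37A2 (0.55), GstD3 (0.52) and GstE9 (0.51). In ap56f against OregonR the same list had 4 plus and 11 minus, with GstD3 at -0.39; its median there was near 0 and changed sides with the scaling. Larval serum and fat body genes had 7 plus and 2 minus of 10 (7 and 2 adjusted over the list alone; median 0.23, camera adjusted p = 0.00041), led by the sterol carrier Npc2e (1.09) and Adh (0.53).

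Cytochrome P450 genes had 18 plus and 4 minus of 73 (21 and 4 adjusted over the list alone; median 0.06, camera adjusted p = 0.015, and 0.23 with an estimated correlation), with Cyp28a5 at 1.12 and Cyp6a20 at 1.00. Phototransduction genes had 0 plus and 3 minus of 17 (5 minus adjusted over the list alone; median -0.05, camera adjusted p = 0.0092, and 0.058 with an estimated correlation): Arr2 (-0.50), Pdh (-0.32) and Gbeta76C (-0.23). Cytosolic ribosomal protein genes had 1 plus and 6 minus of 38 (1 and 7 adjusted over the list alone; median -0.05, camera adjusted p = 0.0092, and 0.17 with an estimated correlation). Cuticle genes had 3 plus and 10 minus of 70 (3 and 10 adjusted over the list alone; median -0.01, camera adjusted p = 0.031, and 0.18 with an estimated correlation), among them Acp65Aa (-0.67) and Cpr49Ah (-0.62); without array 68 or 73 the camera adjusted p was 0.053 and 0.066. Accessory gland genes had 7 plus and 0 minus of 20 (8 and 1 adjusted over the list alone; median 0.09) and a camera adjusted p of 0.05, which did not pass. Within the 4 batches the medians ran from -0.27 to -0.17 for gut, -0.24 to -0.12 for egg shell, -0.07 to -0.03 for ovary, 0.04 to 0.09 for conjugating enzymes, 0.23 to 0.26 for fat body, 0.03 to 0.07 for P450, -0.08 to -0.01 for phototransduction and -0.07 to -0.02 for ribosomal protein genes. Cuticle medians were 0.01, -0.03, -0.02 and 0.03.

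**Figure D2:**
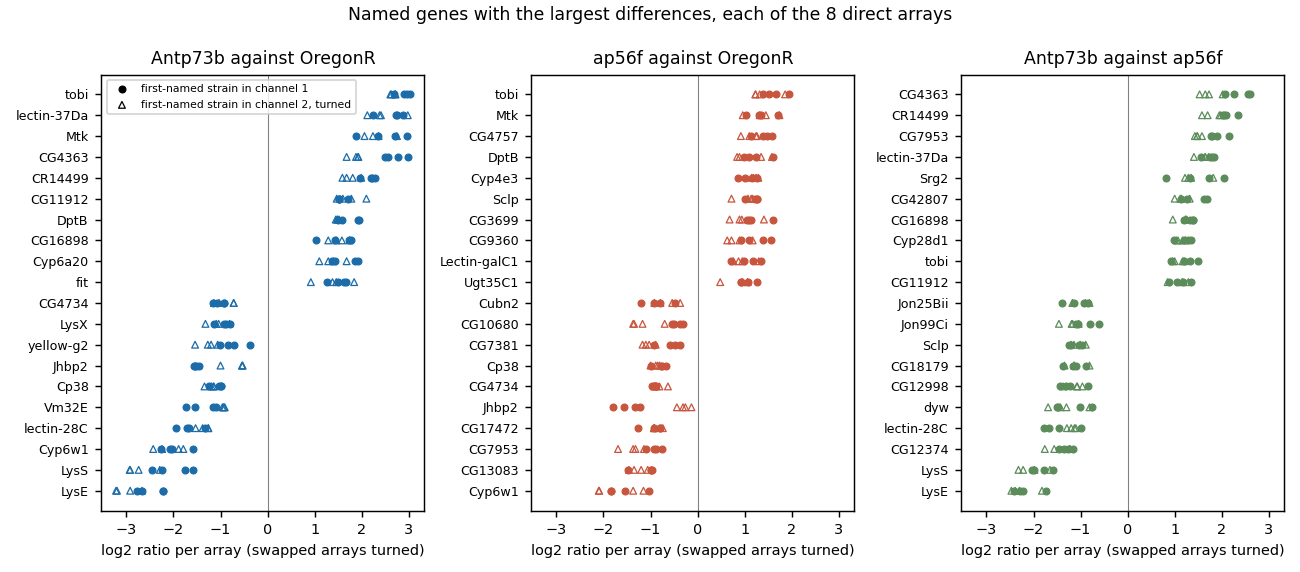
Log2 ratio (horizontal axis) of the genes with the largest differences on each of the 8 arrays that hybridised 2 strains directly, in the 3 comparisons; circles have the first-named strain in channel 1, triangles have it in channel 2 and are turned. Genes were drawn only if they lay on the same side on the direct arrays, such as tobi in Antp73b against OregonR with a mean of 2.78.

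In the remaining lists camera did not pass. fry, which does not compare a list with other genes, passed in Antp73b against OregonR for antenna (fry adjusted p = 0.0015), testis (0.026), muscle (0.0048), eye pigment (0.011), clock (0.0028) and juvenile hormone genes (0.016). It passed in ap56f against OregonR for testis genes (fry adjusted p = 3.2e-06), and in Antp73b against ap56f for antenna (2.8e-05), testis (0.0029), muscle (0.00018), oxidative phosphorylation (0.036) and clock genes (7.1e-05). Antenna and olfaction genes, 18 tested, had 3 plus and 0 minus calls in Antp73b against OregonR, 1 and 2 in ap56f against OregonR and 5 and 0 in Antp73b against ap56f (2 and 0, 1 and 2, and 6 and 0 adjusted over the list alone). The antennal genes a10 and a5 stood at -0.51 and -0.36 in ap56f against OregonR and at 0.42 and 0.43 in Antp73b against ap56f. Homeotic, selector and wing genes, 13 tested, had 1 and 0, 1 and 0, and 2 and 1 calls in the same order of comparisons (1 and 0, 1 and 0, and 2 and 2 adjusted over the list alone), with the homeotic gene Dfd at 0.34 in Antp73b against OregonR. Testis genes, 17 tested, had 1 and 5, 0 and 6, and 4 and 1 (1 and 6, 0 and 7, and 4 and 1 adjusted over the list alone). Muscle genes, 20 tested, had 6 and 4, 1 and 2, and 7 and 3 (7 and 4, 1 and 2, and 8 and 4 adjusted over the list alone), and the myofilament gene Mf stood at 0.51 in Antp73b against OregonR. Heat shock genes, 10 tested, had 4 and 2, 2 and 2, and 3 and 4 (4 and 2, 2 and 2, and 4 and 4 adjusted over the list alone), with Hsp26 at -0.69 in Antp73b and -0.50 in ap56f against OregonR. Oxidative phosphorylation genes, 66 tested, had 5 and 3, 2 and 4, and 7 and 3 (3 and 3, 2 and 2, and 7 and 3 adjusted over the list alone), and the complex I gene ND-B8 stood at -0.70 in Antp73b and -0.75 in ap56f against OregonR. Circadian clock genes, 12 tested, had 4 and 1, 0 and 1, and 4 and 0, with the clock gene tim at 0.43 in Antp73b against OregonR and 0.34 against ap56f. Juvenile hormone genes, 11 tested, had 2 and 2, 2 and 2, and 0 and 1, and the hormone response gene Kr-h1 stood at 0.36 in Antp73b and 0.34 in ap56f against OregonR. Eye pigment genes, 13 tested, had 2 and 0, 0 and 0, and 0 and 0, and for clock, juvenile hormone and eye pigment genes the counts adjusted over the list alone were the same. For these lists camera adjusted p ran from 0.066 to 1. Lists that passed in another comparison missed the threshold for immune effectors in Antp73b against ap56f (5 and 1 calls, camera adjusted p = 0.12), and in ap56f against OregonR for gut digestion (10 and 8, 0.058), cuticle (10 and 5, 0.067), ribosomal protein (1 and 2, 0.54), conjugating enzyme (0.85) and fat body genes (3 and 3, 0.66). In Antp73b against OregonR they missed it for ribosomal protein (2 and 3, 0.13) and cuticle genes (6 and 8, 0.82). Adjusted over the list alone these counts were 6 and 1, 12 and 8, 10 and 5, 1 and 1, 4 and 11, 3 and 3, 2 and 3, and 6 and 8. Among these, fry passed for immune effectors in Antp73b against ap56f (fry adjusted p = 1e-06). It also passed for gut digestion (0.0048) and cuticle genes (0.042) in ap56f against OregonR and ribosomal protein genes in Antp73b against OregonR (0.013), and not for the others. Of 60 list tests, 24 passed with a preset correlation of 0.01 and 15 with an estimated correlation, and fry, which asks whether a list moves 1 way on balance, passed in 41. Lists that still passed with an estimated correlation had a larger camera adjusted p. It was 1.8e-06 for egg shell and yolk genes in both comparisons with OregonR. For ovary germline genes it was 5e-04 in Antp73b against OregonR, 0.0049 in ap56f against OregonR and 0.048 in Antp73b against ap56f. The list median, mean and camera side differed in sign in 7 tests, of which 0 passed.

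**Figure D3:**
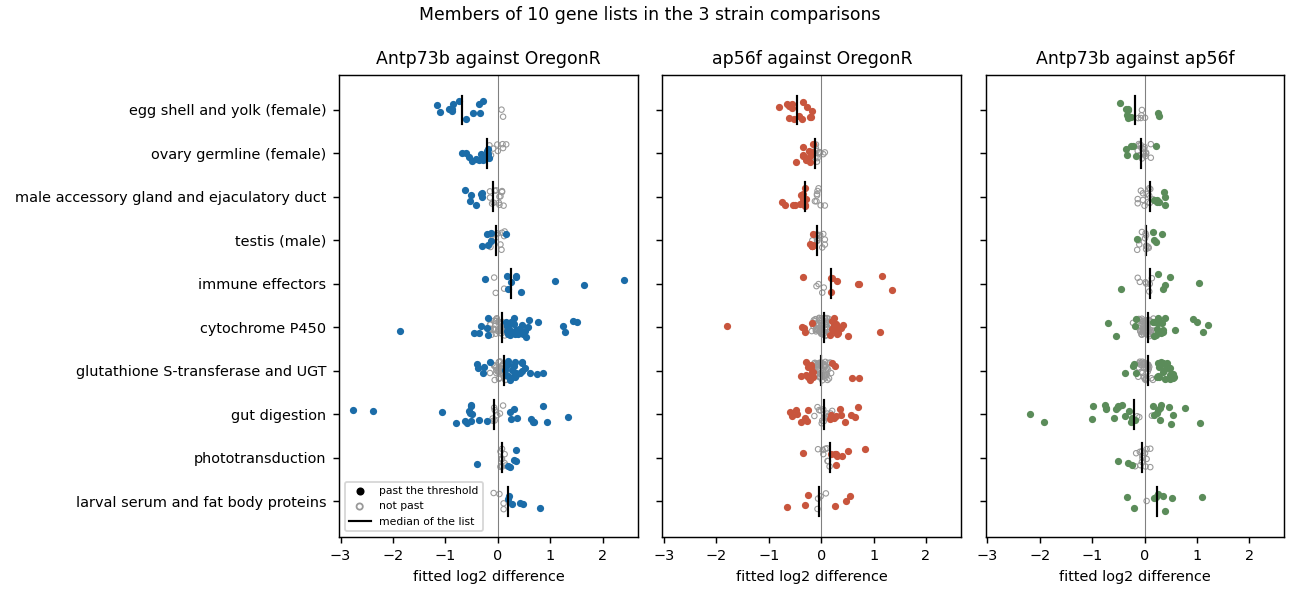
Fitted log2 difference (horizontal axis) of each member of 10 gene lists in the 3 comparisons; filled points pass an adjusted p of 0.05, open points do not, and bars are medians. Egg shell and yolk genes lie on the minus side against OregonR, with medians of -0.67 and -0.46; the median of the conjugating enzymes in ap56f against OregonR is near 0 and changes sides with the scaling.

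Both mutant strains shared part of their difference from OregonR. OregonR stood apart from both other strains on the same side for 1232 elements, Antp73b for 1277 and ap56f for 585, and 422 elements differed in all 3 comparisons, with ap56f in the middle for 60.2% of them. The comparisons with OregonR had 578 calls in common on the plus side, 654 on the minus side and 89 on opposite sides. Independent lists would share 123 and 132. Across elements, which are not independent, their differences correlated with r = 0.588 (Spearman's rho = 0.579). Both comparisons use the same OregonR hybridisations, and simulated unchanged strains gave r = 0.5 and 0 shared calls in limma. With no strain changed few or no elements are called, so this 0 is no background for the shared calls. The covariance was 0.0154 against 0.00175 simulated, a difference of 0.0137, and 0.0141 when each comparison used its own direct arrays (r = 0.486). Separate arrays may still hold the same OregonR RNA, since the number of extractions is not given. A peculiarity of that RNA would give the same sharing and was not tested.

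Genes on chromosome 4 were called more often in both mutant strains against OregonR. In Antp73b 21 of 53 genes were called (39.6%, exact 95% interval 26.5 to 54), against 23.7% on the other arms (Fisher's exact test, odds ratio 2.11, adjusted p = 0.034), and 19 of them lay on the plus side. In ap56f it was 16 of 53 (30.2%, exact 95% interval 18.3 to 44.3), against 15.8% on the other arms (Fisher's exact test, odds ratio 2.3, adjusted p = 0.034), with 14 on the plus side. Between the mutant strains 8 of 53 were called (odds ratio 0.885). Both comparisons with OregonR share the OregonR arrays. With calls at an adjusted p of 0.01 the odds ratios were 2.07 and 1.74 and did not pass, and no gene on chromosome 4 reached 2-fold. Genes on X were called less often in Antp73b against ap56f, 13.7% against 17.3% (odds ratio 0.761, Fisher's exact adjusted p = 0.0068). In Antp73b against OregonR, 26.3% of genes on 2L (odds ratio 1.18) and 21.4% on 3L (odds ratio 0.844) were called, with a Fisher's exact adjusted p of 0.032 each. The arms that carry Antp (3R, odds ratios 1.07, 1.01 and 1.03) and ap (2R, odds ratios 0.987, 0.952 and 1.13) did not pass in any comparison. Of 18 arm tests 5 passed, and genes on an arm are not independent.

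Exchanging the colours was read after removal of the dye term, without which the orientations correlated with r = -0.129, -0.389 and -0.249 across elements. Elements called from 1 orientation and the self-hybridised arrays (1345, 626 and 878) had the same side in the other orientation for 84.1%, 73% and 74.1% in Antp73b against OregonR, ap56f against OregonR and Antp73b against ap56f. Over all elements, which are not independent, the orientations then correlated with r = 0.539, 0.272 and 0.332; both use the same self-hybridised arrays, and an error in their mean moves the orientations apart. The dye term itself was called for 9104 elements (61.2%), with a median fold of 1.11, and all 101 elements at 2-fold or more had no gene listed. Direct and indirect differences around the triangle of strains differed at 0 of 14866 elements in limma, with 564 at an unadjusted p under 0.05. The self-hybridised ratio differed between strains at 0 elements in limma, with 649 at an unadjusted p under 0.05. In a test of whether strain differences varied between batches, limma called 0, 0 and 0 elements by place (907, 708 and 798 at an unadjusted p under 0.05) and 0, 1 and 5 by parity (710, 970 and 802), while the dye term varied by place at 2955 elements and by parity at 119. The elements that varied by parity, named here after their values were seen, were those of CG17032, RfC3, Srg2 and CG7120 in Antp73b against ap56f (limma adjusted p = 6.8e-06, 0.014, 0.037 and 0.037) and an element with no gene listed in that comparison and in ap56f against OregonR (limma adjusted p = 0.037 and 0.0038).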

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

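The checks for outlying arrays follow a rule chosen before the data were examined. They covered array measures, in 36 tests of 4 arrays each, and the 8 direct array values of 66 named gene results, and 7 values stood apart from the others of their group. Chance alone marks about 1 in 20 tests.

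Array 69 (ap56f in channel 1, OregonR in channel 2) had 28939 spots with a value, against 30086 to 30213 on the other arrays of its group. Array 64 (Antp73b in channel 1, OregonR in channel 2) had a correlation of duplicate spots of 0.5165, against 0.6007 to 0.6123. In ap56f against OregonR, array 54 gave 0.72 for Sclp (others 1.01 to 1.26), 0.48 for Ugt35C1 (others 0.92 to 1.26) and -0.63 for CG4734 (others -0.96 to -0.81). Each of these 3 values lies closer to 0 than those of the other arrays, and the 3 genes kept their calls without array 54. Array 68 gave -1.26 for CG17472, against -0.93 to -0.74 on the others. In Antp73b against ap56f, array 71 gave 0.96 for CG16898, against 1.2 to 1.4. No biological explanation was tested for these single values, since the arrays of a group hold the same pair of strains.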

How the results depend on the processing

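The centring on a trimmed mean, the single spots, the fit of listed elements only and the batch fits were chosen after seeing the data. Of 140 values under settings other than leaving out an array, 93 stayed within 1.5 times or on their side of the threshold, 43 moved, 2 weakened and 2 reversed. Counts were compared by their totals, so a shift between the plus and minus sides does not enter these labels. Calls are given in the order Antp73b against OregonR, ap56f against OregonR, Antp73b against ap56f (3277, 2335 and 2288).

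Stricter rules gave fewer calls by construction: 2176, 1324 and 1451 at an adjusted p under 0.01, 201, 116 and 129 at 1.5-fold, and 377, 194 and 233 with limma's treat at 1.2-fold. At 0.01 a strain stood apart on 1872 elements (OregonR 712, Antp73b 812, ap56f 348), and the shared calls against OregonR were 712. At 1.5-fold in both comparisons it was 151 (49, 71 and 31). Fewer arrays also gave fewer calls: 1972, 715 and 1091 from the 8 direct arrays (389 shared calls), 1345, 626 and 878 with the first-named strain in channel 1 only. Within batches, the counts that moved were 1460 for ap56f against OregonR (first 2 arrays), 1597, 876 and 935 (last 2), 1790, 834 and 1051 (even) and 1732, 1347 and 1213 (odd). Without a dye term ap56f against OregonR had 1382 and Antp73b against ap56f 1486 calls. The colours are balanced between the strains, so on elements with a value on all arrays this leaves the differences unchanged. It puts the dye effect into the residual spread. The first spot alone gave 1300 and 1259 in these comparisons, and the second spot 1406 in ap56f against OregonR; averaging fewer spots leaves more noise. The dye term's plus share was 45.1%, but 64.1% from the first spot and 31.5% from the second.

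Of 251 named gene calls, 213 held with the 8 direct arrays, 228 without a dye term, 249 without centring, 247 with the trimmed mean, 251 with blocks, and 226, 202, 203 and 207 within the first 2, last 2, even and odd arrays. The losses included ap in Antp73b against ap56f (direct 0.19, no dye term 0.055, first 2 0.59, even 0.4, odd 0.087) and against OregonR in ap56f (last 2 0.065, even 0.2), Arr1 (last 2 0.053, difference 0.29) and Dfd (even 0.07, difference 0.27) in Antp73b against OregonR, and Gbeta76C in Antp73b against ap56f (last 2 and even, 0.1 each, difference -0.21 in both); values other than differences are limma adjusted p.

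Camera passed 24 list tests, and 15 with an estimated correlation. It lost 0, 3, 2 and 3 of these calls within the first 2, last 2, even and odd arrays, all among phototransduction, ribosomal protein and cuticle genes, and 1 with the 8 direct arrays (gut in Antp73b against OregonR, 0.07). Calls gained were accessory gland (direct 0.015, first 2 0.029, odd 0.028, not centred 0.048, place as a block 0.05 rounded), immune (direct 0.027, odd 0.038) and antenna (even 0.0083) in Antp73b against ap56f. In ap56f against OregonR they were testis (direct 0.015, even 0.014), gut (not centred 0.048, first 2 0.046) and cuticle (even 0.043). Arm tests passed 5 times, 0 times for calls of at least 2-fold and 3 times at 0.01. The chromosome 4 odds ratios turned to 0 and 0 for calls of at least 2-fold, since no gene there reached 2-fold, and were 2.07 and 1.74 at 0.01, no longer past the threshold, with fewer called genes.

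Leaving out each array in turn moved 0 of 396 values beyond 1.5 times. The counts ran from 2992 to 3366, 1970 to 2362 and 2048 to 2328, and from 8963 to 9151 for the dye term. A strain stood apart on 2851 to 3135 elements (OregonR 1100 to 1250, Antp73b 1163 to 1288, ap56f 522 to 597), 0 to 0 elements failed the triangle in limma, where 564 had an unadjusted p under 0.05, 23 to 27 list tests passed, and 246 to 251 of 251 named gene calls held. List calls gained this way, by camera adjusted p, were accessory gland in Antp73b against ap56f (19 arrays, from 0.031), gut in ap56f against OregonR (arrays 50, 56, 57 and 69, from 0.029), testis (51, 64, 67 and 73, from 0.04) and cuticle (57, 60 and 67, from 0.027) in the same comparison, and antenna in Antp73b against ap56f (73, 0.025). No paired analysis was possible because the array numbers are unique to each array. Rounding to 1 decimal limits small differences, and signal over background is not given in the sources used here.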

Other observations

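The tests of batches, of the share of females, of copy number, of a dye bias that varies between arrays, of random gene sets and of the antenna genes were chosen after their results were seen. Splits of the arrays, with strain labels permuted over elements complete on all arrays, tested whether chance could give as many calls. Only 1 split of 100, the real one, reached its count of calls in Antp73b against OregonR (3105, highest other 357). The same held in ap56f against OregonR (2291, highest other 1) and in Antp73b against ap56f (2228, highest other 1). Likewise only the real split reached the count of elements on which a strain stood apart (3040, highest other 0). A chance fall of single arrays to the strains is therefore unlikely as the source of these counts. An effect shared by the arrays of a group, which carry consecutive array numbers, was not tested by these splits. A chance difference between the RNA samples of the strains was not tested, since the number of extractions is not given. For the triangle of strains and the self-hybridised ratios limma called 0 elements (564 and 649 at an unadjusted p under 0.05), and 100 of 100 splits gave as many, with a highest other of 0 and 1; with a real count of 0 this could not come out otherwise and decides nothing.

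Egg shell, yolk and ovary genes lay on the minus side in both mutant strains against OregonR. Dye bias was tested by the median of these genes in each orientation, and the value closest to 0 was -0.21, so the side did not turn with the dye. The egg shell and yolk median closest to 0 within any batch by place or parity was -0.44, so the side did not rest on the arrays of a particular batch. Place and parity fell evenly across the groups and could not by themselves set the strains apart, so these medians do not decide on a batch as the cause. A difference between the RNA samples of the strains would be the same in every such batch. It was not tested and stays open. A different share of females in the RNA would by itself move male accessory gland genes to the other side. These lay on the minus side too, with a camera adjusted p of 0.00038 for the strain with the larger value. A share of females alone therefore does not give all these differences from OregonR. It may still underlie the egg shell and ovary differences if another cause moved the accessory gland genes. In Antp73b against ap56f a different share of females stays open as well. Egg shell and ovary genes lay on the minus side there (medians -0.19 and -0.07), and accessory gland genes on the plus side (0.09). These sides are what a different share of females would give, but the accessory gland list did not pass (camera adjusted p = 0.05). Testis genes, also male, had a median of 0.03 there (camera adjusted p = 0.65). Age, feeding state and genetic background of the strains stay open and untested, and a biological difference between the strains may be the source as a hypothesis only.

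Chromosome 4 genes lay on the plus side in both mutant strains against OregonR, with medians 0.08 (SE 0.027) and 0.10 (SE 0.021) above those of other genes. These SEs come from resampling the 53 genes and do not measure the spread between arrays. Random sets of 53 genes had a median as far in 4 and 0 of 10000 draws, so such a median is rare among random sets. The arm was picked after its calls were seen, with no allowance for the choice among arms. Genes on a chromosome are also not independent, so the draws do not exclude chance. The dye was tested by orientation: the lowest value was -0.05, with 0.13 and -0.05 in Antp73b and 0.20 and 0 in ap56f. Opposite signs had been set beforehand as the mark of a dye bias, and they came out in Antp73b. That mark was wrong by the design, since a dye offset adds to 1 orientation and subtracts from the other whether or not the strains differ; the offset on these genes was 0.153 on self-hybridised arrays. With a dye term over 36 arrays the differences were 0.083 and 0.104 (SE between arrays 0.021 each). This argues against a constant dye bias, and against one that varies independently between arrays, as the whole cause. A dye bias that moves with the array number was not covered and stays open. Arrays 50 to 57 had OregonR in channel 1 against the mutant strains, and arrays 62 to 69 had it in channel 2. Copy number cannot be told apart: the difference was 0.1 in the strain with the larger value, and how transcripts respond to a copy here was not measured. A tighter bound on its size, used at first, was dropped for that reason. Genetic background stays open and untested.

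Genes beside each other on an arm were called on the same side more often than chance placement gives. In Antp73b against OregonR 386 of 10070 neighbouring pairs were called on the same side, against a mean of 291 and a highest of 346 over 1000 placements of the calls within arms. Without pairs of the same family, by the start of their symbols, 336 pairs remained, against a highest of 331. Pairs in which both genes have only a CG or CR number were kept, so unnamed families stayed in. Families as named explain part of the excess, and whether families explain all of it cannot be told from this count. The counts were 195 (highest 165) in ap56f against OregonR and 238 (highest 200) in Antp73b against ap56f, where 1 of 1000 placements gave as many without families (193). The longest runs in Antp73b against OregonR were 9 genes on 2R from Cyp4e2 to Mal-A8, all plus, and 8 genes of the GstD cluster on 3R, all plus. Both were chosen after their values were seen. Signal shared between near-identical genes, shared regulation and stretches of differing sequence between the strains may each add to such runs, and none was tested beyond these 336 pairs.

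Antenna and olfaction genes were tested as a hint on the direction of the ratio, since Antp73b flies may lack part of their antennae. If the ratio is channel 1 over channel 2, these genes would lie on the minus side in Antp73b. They lay on the plus side for 12 of 18 genes against OregonR (exact binomial p = 0.24) and for 16 of 18 against ap56f (exact binomial p = 0.0082). The result against OregonR leaves the direction open, and the larger p of 0.24 decides between neither reading.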
